A study of Mus musculus with 28 samples.

How the data were processed

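RNA-seq of poly(A) RNA measured gene expression in 28 mouse libraries, 2 for each of 14 groups: WT and K36M cells at d0 (MEFs), d2, d4, d6 and d8 of reprogramming, as passaged iPSCs, and as MEFs without OKSM, written noOKSM. Per the labels' protocols, MEFs grew in DMEM with serum, reprogramming cells in a medium called AGi and iPSCs in one called S/L, RNA was extracted with an miRNeasy kit, libraries were made with a directional NEBNext Ultra kit and reads came from an Illumina HiSeq instrument. The authors deposited 1 table of raw read counts per gene, which the values themselves show as whole numbers with totals that differ between libraries. Per the submitters' processing notes, STAR 2.5.0, HTSeq 0.11.2 and edgeR were among the tools and mm9 was the build; the strand setting, the annotation and the handling of reads that match several places are not given in the sources used here. Counts of genes with near-identical copies (keratins, tubulins, histones, retrogenes such as Rpl10l), of overlapping genes and of antisense pairs are therefore uncertain. Of 37620 gene IDs, 37205 were found in GENCODE vM1, whose coordinates are on mm9 and are given counting from 1. The table holds no count outside genes, and its 37 mitochondrial genes are all at 0, so neither unassigned reads nor mitochondrial RNA could be checked. Each column was matched to a sample by its name, and no column was left over (0 unused). The columns of the iPSC and noOKSM libraries carry no stage in their names, so their stage comes from the sample with the same library number, genotype and replicate number.

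Counts were analysed in R 4.3.3 with edgeR 4.0.16. Library sizes were scaled by TMM, genes with few counts were dropped by filterByExpr (minimum count 10, minimum total 15), and a robust quasi-likelihood model was fitted to all 14 groups at once, which left 16932 genes, 14 residual degrees of freedom and 1 shared estimate of spread. Contrasts compared K36M with WT at each of the 7 stages, WT at each later stage with WT d0, the K36M difference at d2, d4, d6, d8 and iPSC jointly with that at d0 (a test on 5 coefficients), and the K36M difference in noOKSM with that at d0. A separate model of the 16 libraries of d2 to d8, with day as a covariate, gave the difference shared by these days (15954 genes, 11 residual degrees of freedom). Changes of the K36M difference between days stay in its residual. P-values were two-sided and adjusted by Benjamini-Hochberg over all genes of a contrast, and genes with an adjusted p below 0.05 were taken to differ. CPM values are counts divided by the TMM-scaled library size and expressed on the usual CPM scale, as mean ± SD of 2 libraries, and log2 fold changes carry a standard error equal to their size divided by the square root of the F statistic.

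Gene lists were tested with camera in limma 3.58.1 (preset correlation 0.01, lists with at least 3 measured members), 192 tests in all over 24 lists and 8 contrasts, adjusted together; camera with an estimated correlation and fry, which tests a list by itself and not against other genes, were run beside it. Of these tests 82 passed, 28 passed with an estimated correlation and 121 passed with fry. The lists were the 4 reprogramming factors, pluripotency, epithelial, mesenchymal and fibroblast, contractile and TGF-beta-responsive, Hox, developmental regulators, germline, 2-cell stage, H3K36 and PRC2 enzymes, DNA methylation enzymes, imprinted, cell division, senescence and p53 targets, interferon response and glycolysis genes, and markers of macrophages, endothelium, skeletal muscle, neurons, keratinocytes, trophoblast, primitive endoderm, adipocytes, and cartilage and bone; the sex chromosome genes, the last of the 26 lists, are read per library and not tested. The samples' groups, the tests, the lists, the rule for naming genes and all alternatives except those named below were chosen before the data were examined. In list counts, genes that rose or fell passed the test over all genes, and the number "adjusted over the list alone" is of members that pass when only the list is adjusted. Some genes stand in 2 lists (among them Hand1, Gata4 and Eomes), 3 of the listed symbols were not found, and Zeb1 could not be used because its 2 records hold only 7 and 22 counts over all libraries.

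Genes named in the text come from a fixed rule. It takes, per contrast, the 5 genes with the largest rise and the 5 with the largest fall (10 and 10 over d2 to d8 and for WT iPSC against WT d0) among those that passed, had a mean of at least 5 CPM, had groups that did not overlap (over d2 to d8, the same direction on all 4 days) and had a symbol that is not a predicted, clone, pseudogene or ribosomal protein name. It adds, per list and contrast, up to 4 members that passed with the largest changes, or up to 2 with the highest CPM where none passed, and a fixed set (H3f3a, H3f3b, the 4 factors, Nanog, Cdh1, Epcam, Zeb1, Zeb2, Snai1, Snai2, Twist1, Twist2, Col1a1, Acta2, Thy1). Only part of the genes so taken are printed. The position score is the mean log2(CPM + 1) of genes at least 4-fold higher in WT iPSCs than in WT d0 minus that of genes at least 4-fold lower. It was scaled to 0 at WT d0 and 100 at WT iPSC. The tested libraries of d2 to d8 were not in the contrast that chose its genes. They entered the fit only through the filter, the scaling and the shared estimate of spread. Folds against a group at 0 counts are given as a lower bound from 3 counts over the group, and folds against 1 to 3 counts as a ratio with a 95% interval. Both cover counting error only. Over d2 to d8 the fitted fold changes are given without such a bound.

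Total counts of 17507521 to 35622279 per library make counting error small for most genes named. On simulated counts for the d4 contrast (16384 genes), the model recovered 72%, 88%, 100% and 100% of genes changed 1.5-, 2-, 4- and 8-fold, and called 12 of 16159 unchanged genes. For d2 to d8 (14858 genes) it recovered 96%, 100%, 100% and 100% and called 7 of 14633 unchanged genes. A list raised in the simulation was found in both and 0 of 23 unchanged lists were called, and a score difference of 50 was recovered as 50.9. A GC trend put into 1 library (rho 0.904) was taken to 0.019 by the correction described next. Genes were drawn independently of each other, with the same fold on every day. The simulation therefore does not cover lists of correlated genes or K36M differences that change between days. Replicates of each group differed by more than sampling noise (chi-square per degree of freedom 2.35 to 65.4), so none were merged.

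Alternatives were RLE factors, DESeq2 1.42.0, no filter and a stricter filter of 5 CPM, a 2-fold threshold, only the compared groups in the fit, no noOKSM libraries, no robust estimation, a replicate block, for d2 to d8 the average of the 4 days in the fit of all groups, each library left out in turn, and for the score other pseudocounts (0.1 and 5), gene choices and averages. Added after the data were seen were a correction of each library for transcript length and GC content (natural splines as offsets; 98.3% of 10961 genes at 5 CPM or more had both values and 97.5% an annotated 3' UTR) and fits without the d6 libraries. No sample was left out of the main analysis. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.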

Results

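Poly(A) RNA was sequenced from mouse cells taken while fibroblasts were turned into induced pluripotent stem cells (iPSCs), to ask how a K36M histone H3 alters that change of cell identity. K36M is a lysine-to-methionine substitution in the tail of histone H3. Mouse embryonic fibroblasts (MEFs) labelled WT or K36M were sampled at d0, at d2, d4, d6 and d8 of reprogramming with the factors Oct4, Klf4, Sox2 and Myc (OKSM), as passaged iPSCs, and as MEFs without OKSM. Each of the 14 groups held 2 libraries, 28 in all. Total gene counts per library ran from 17507521 in K36M iPSC replicate 1 to 35622279 in WT noOKSM replicate 1, and 25652 of 37620 listed genes had at least 1 count. The labels do not say whether replicates came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

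H3f3a, which codes for histone H3.3 and lies on chromosome 1 from 182730963 to 182744074 of mm9, was read first in each group. Library names give H3.3 for the WT cells and K36M for the others, which points to H3.3 as the histone, although no label says which of its genes carries K36M. In WT it stood at 46.2 ± 4.13 CPM at d0, 186 ± 12.9 at d2, 223 ± 16.3 at d4, 215 ± 4.16 at d6, 193 ± 2.56 at d8, 60.9 ± 6.08 in iPSCs and 159 ± 5.76 in MEFs without OKSM (mean ± SD, n = 2). In K36M the values in the same order were 47.1 ± 2.32, 160 ± 12.8, 178 ± 10.8, 185 ± 6.79, 121 ± 9, 62.3 ± 2.23 and 115 ± 22.2 CPM. K36M was lower at d8, with a log2 fold change of -0.68 ± 0.111 (± SE, edgeR adjusted p = 1.63e-05). It was also lower in MEFs without OKSM, with -0.46 ± 0.111 (edgeR adjusted p = 0.00251), while the log2 fold change at d0 was 0.03 ± 0.116 (edgeR adjusted p = 0.93). Without K36M noOKSM replicate 1 the difference in MEFs without OKSM was -0.28 and did not pass the test. A gene count cannot tell transgene from endogenous reads, nor a K36M from a WT sequence, so H3f3a does not check the genotype labels.

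The factors themselves were read in the same way, with the same limit on transgene reads. Pou5f1, the gene of Oct4, went from 1.72 ± 0.531 CPM at d0 to 277 ± 15.7 at d2 in WT and from 2.45 ± 0.267 to 271 ± 25.1 in K36M. At d2 the K36M to WT log2 fold changes were -0.03 ± 0.183 for Pou5f1, -0.09 ± 0.17 for Sox2, -0.06 ± 0.129 for Klf4 and -0.15 ± 0.198 for Myc, and none passed the edgeR test (adjusted p = 0.961, 0.795, 0.819 and 0.705). Pou5f1 was higher in K36M from d4, with a log2 fold change of 1.42 ± 0.187 at d4 and 2.25 ± 0.191 at d6 (edgeR adjusted p = 1.18e-06 and 8.62e-10). Klf4 was lower in K36M at d6, with a log2 fold change of -1.59 ± 0.134 (edgeR adjusted p = 4.11e-10). As a list the 4 factors showed no shared shift over d2 to d8 (1 rose, 1 fell; 3 adjusted over the list alone; camera adjusted p = 0.96).

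The WT series set the reference course from fibroblast to iPSC. Cdh1, which codes for the epithelial adhesion protein E-cadherin, stood at 0.188 ± 0.266 CPM in WT MEFs and 599 ± 26.7 CPM in WT iPSCs, and Nanog, a core pluripotency transcription factor, at 0.521 ± 0.129 and 429 ± 31.1 CPM (mean ± SD, n = 2). Lin28a, an RNA-binding protein of pluripotent cells, and Fgf4, a growth factor made by them, had 0 counts at d0 and were at least 4490-fold and 4570-fold higher in iPSCs, taking 3 counts over the group as the floor. Genes of the contractile fibroblast fell, with log2 fold changes of -6.73 ± 0.183 for Acta2, a smooth muscle actin, -7.21 ± 0.191 for Cnn1, calponin, and -8.29 ± 0.237 for Actg2, another smooth muscle actin (± SE; edgeR adjusted p = 5.56e-19, 4.08e-19 and 1.3e-18). Between WT d0 and WT iPSCs 13114 of 16932 tested genes differed in the edgeR test (6789 higher, 6325 lower). All 25 pluripotency genes, 24 of 25 epithelial genes and 20 of 20 cell division genes rose (25, 25 and 20 adjusted over the list alone), and the other epithelial gene fell. Of 24 mesenchymal and fibroblast genes 22 fell and 2 rose, and 24 of 25 Hox genes fell (24 and 25 adjusted over the list alone).

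Epithelial and pluripotency genes rose step by step within the WT series. Compared with d0, 10 epithelial genes had risen at d2, 21 at d4, 24 at d6 and 25 at d8 (11, 22, 24 and 25 adjusted over the list alone, both directions together), and 2 had fallen at d2. For the 25 pluripotency genes the numbers were 6, 10, 18 and 24 (8, 12, 19 and 25 adjusted over the list alone), and 2, 2, 1 and 1 had fallen. The mesenchymal and fibroblast genes had already moved at d2, when 22 of 24 fell and 1 rose (23 adjusted over the list alone). All 20 cell division genes had risen at d2, 12 at d4, 3 at d6 (3 others fell) and 12 at d8 (20, 12, 6 and 12 adjusted over the list alone). All 4 factor genes were higher than at d0 on each of these days (4 adjusted over the list alone). In the edgeR test 9779 genes differed from d0 at d2, 9717 at d4, 9995 at d6 and 10844 at d8. Per the labels MEFs, reprogramming cells and iPSCs were grown in different media, so time and medium cannot be told apart in comparisons with d0 or with iPSCs, while the cells of d2 to d8 shared 1 medium.

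Over d2 to d8 the K36M cells held more epithelial and pluripotency RNA and less fibroblast RNA than WT cells of the same day. Zfp42, a marker of naive pluripotent cells, had a K36M to WT log2 fold change of 5.77 ± 0.402 and Lin28a of 5.54 ± 0.474 (edgeR adjusted p = 8.37e-08 and 5.67e-07, n = 8 libraries per genotype). WT held 1, 0 and 3 Zfp42 counts over both libraries at d2, d4 and d6, so the size of its fold is uncertain. Lefty2, an inhibitor of Nodal signalling, rose with 5.95 ± 0.506, and Krt7, a keratin of simple epithelia, with 5.53 ± 0.28 (edgeR adjusted p = 5.38e-07 and 5.66e-09). All 4 went the same way on all 4 days, which the rule for naming genes requires. Fmod, the matrix proteoglycan fibromodulin, fell with -7.14 ± 0.804, and Prelp, another matrix proteoglycan, with -5.69 ± 0.804 (edgeR adjusted p = 5.75e-06 and 3.98e-05). Il1rn, the interleukin-1 receptor antagonist, fell with -6.07 ± 0.628 (edgeR adjusted p = 2.74e-06). The log2 fold changes were 3.11 ± 0.422 for Cdh1, 3.67 ± 0.679 for Nanog and 3.25 ± 0.499 for Epcam, an epithelial adhesion molecule (edgeR adjusted p = 2.79e-05, 0.000354 and 8e-05). They were -4.0 ± 0.679 for Prrx1, a mesenchymal transcription factor, and -2.85 ± 0.507 for Twist1, a driver of epithelial-mesenchymal transition (edgeR adjusted p = 0.00018 and 0.000263). In mm9 Cdh1 lies on chromosome 8 from 109127251 to 109194146, Epcam on chromosome 17 from 88035319 to 88050446 and Nanog on chromosome 6 from 122657507 to 122664651. Of 15954 tested genes 9328 differed (4822 higher and 4506 lower in K36M), 4069 of them by at least 2-fold. Without the d6 libraries, where one K36M replicate stood apart, 8678 genes differed.

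Several fixed groups of genes moved mostly one way over d2 to d8, although most of these list tests did not pass once the correlation between genes was estimated. In this model K36M differences that change between days stay in the residual and so enter the SE and the estimated correlation. Day by day, the epithelial list passed camera with an estimated correlation at d2, d4, d6 and d8 (adjusted p = 1.29e-06, 1.2e-06, 6.69e-07 and 0.000716). The mesenchymal list did so only at d8 (adjusted p = 0.0434). Of 25 epithelial genes all rose (25 adjusted over the list alone, camera adjusted p = 2.41e-13, adjusted p = 0.187 with an estimated correlation). Among them Prss8, a membrane serine protease, had a log2 fold change of 4.63 ± 0.405. Of 25 pluripotency genes all rose (25 adjusted over the list alone, camera adjusted p = 9.65e-12, adjusted p = 0.0792 with an estimated correlation). Of 20 cell division genes all rose (20 adjusted over the list alone, camera adjusted p = 1.96e-06, adjusted p = 0.413 with an estimated correlation). The mitotic kinase gene Bub1 rose with 1.18 ± 0.202. Of 24 mesenchymal and fibroblast genes 21 fell and 1 rose (22 adjusted over the list alone, camera adjusted p = 1.84e-07, adjusted p = 0.38 with an estimated correlation). The gene that rose was Lum. Of 20 contractile and TGF-beta-responsive genes 17 fell and 1 rose (18 adjusted over the list alone, camera adjusted p = 1.43e-09, adjusted p = 0.0434 with an estimated correlation). Ltbp2, a matrix protein named for the family of latent TGF-beta binding proteins, fell with -3.91 ± 0.491 and Acta2 with -2.77 ± 0.301. Of 25 Hox genes 22 fell (22 adjusted over the list alone, camera adjusted p = 1.75e-08, adjusted p = 0.397 with an estimated correlation). Hoxa3 fell with -3.99 ± 0.341. Of 17 senescence and p53 target genes 13 fell (13 adjusted over the list alone, camera adjusted p = 9.51e-05, adjusted p = 0.339 with an estimated correlation). The cell cycle inhibitors Cdkn2b and Cdkn1a were among them, with -1.47 ± 0.141 and -1.21 ± 0.226.

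Genes of other lineages also moved over d2 to d8, and several of these lists also rose along the WT series. From WT d0 to WT iPSCs all 16 germline genes rose, 18 of 19 interferon response genes rose and 1 fell. Of 10 trophoblast genes 6 rose and 1 fell, and of 11 keratinocyte genes 5 rose and 1 fell. Of 8 skeletal muscle genes 4 rose and 3 fell (16, 19, 6, 6 and 7 adjusted over the list alone). These rises alone do not set K36M apart from that series. The K36M to WT counts over d2 to d8 follow. Of 16 germline genes 14 rose (14 adjusted over the list alone, camera adjusted p = 0.000465, adjusted p = 0.477 with an estimated correlation). The RNA-binding protein gene Dazl had a log2 fold change of 5.02 ± 0.511 and the meiotic gene Hormad1 of 6.64 ± 0.62. WT held 0 Hormad1 counts at d6, so the size of that fold is uncertain. Of 10 trophoblast genes 9 rose and 1 fell (10 adjusted over the list alone, camera adjusted p = 1.6e-06, adjusted p = 0.0466 with an estimated correlation). Hand1, also a heart and limb regulator, led them with 5.69 ± 0.318, followed by Krt7. WT held 0, 1, 3 and 3 Hand1 counts over both libraries at d2, d4, d6 and d8, so the size of its fold is uncertain. Of 11 keratinocyte genes 8 rose and 1 fell (11 adjusted over the list alone, camera adjusted p = 0.0107, adjusted p = 0.397 with an estimated correlation). Krt5 rose with 4.46 ± 0.477, although keratin reads can be shared among related copies. Of 8 skeletal muscle genes 7 rose (7 adjusted over the list alone, camera adjusted p = 0.00451, adjusted p = 0.196 with an estimated correlation). Actc1, which is cardiac actin, rose with 3.31 ± 0.425 and Des, the desmin gene, with 2.56 ± 0.254. Of 16 interferon response genes 11 rose and 2 fell (13 adjusted over the list alone, camera adjusted p = 0.0124, adjusted p = 0.38 with an estimated correlation). The chemokine gene Cxcl10 rose with 3.07 ± 0.22.

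The following lists did not pass the camera test over d2 to d8. Of 25 developmental regulators 14 fell and 7 rose (23 adjusted over the list alone, camera adjusted p = 0.352). Of 18 H3K36 and PRC2 enzymes 6 rose and 5 fell (11 adjusted over the list alone, camera adjusted p = 0.857). Of 7 DNA methylation enzymes 5 rose and 1 fell (6 adjusted over the list alone, camera adjusted p = 0.195). Of 20 imprinted genes 9 rose and 2 fell (11 adjusted over the list alone, camera adjusted p = 0.229). Of 16 glycolysis genes 8 rose and 1 fell (9 adjusted over the list alone, camera adjusted p = 0.0982). The same held for these markers of other cell types. Among 7 macrophage genes 3 fell and 2 rose (5 adjusted over the list alone, camera adjusted p = 0.352). Among 9 endothelial genes 5 rose and 2 fell (7 adjusted over the list alone, camera adjusted p = 0.0982). Among 12 neuronal genes 2 rose and 2 fell (4 adjusted over the list alone, camera adjusted p = 0.787). Among 8 primitive endoderm genes 3 fell and 2 rose (5 adjusted over the list alone, camera adjusted p = 0.697). Among 3 adipocyte genes 2 fell (2 adjusted over the list alone, camera adjusted p = 0.543). Among 7 cartilage and bone genes 3 rose and 2 fell (5 adjusted over the list alone, camera adjusted p = 0.999). Within these lists Dnmt3b, a de novo DNA methyltransferase, rose with a log2 fold change of 3.24 ± 0.432, Jarid2, a PRC2 cofactor, with 1.15 ± 0.15, and Slc16a3, a lactate transporter, with 3.50 ± 0.398 (edgeR adjusted p = 2.41e-05, 1.94e-05 and 6.24e-06). The median or the mean of the log2 fold changes had the sign opposite to the test in 29 of 192 list tests, of which 1 passed. This was the senescence list, with a median above 0 at d2. At that day the counts were as follows. Of 19 senescence and p53 target genes 7 fell (7 adjusted over the list alone, camera adjusted p = 0.012, adjusted p = 0.189 with an estimated correlation). No gene of the 2-cell stage list was detected well enough to test.

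A score per library placed every sample between WT d0 (set to 0) and WT iPSCs (set to 100), from 3018 genes that rose and 2328 that fell at least 4-fold along the WT series. WT cells reached 31.4 ± 0.174 at d2, 36.5 ± 0.244 at d4, 39.9 ± 1.11 at d6 and 49.2 ± 0.471 at d8 (mean ± SD, n = 2), while K36M cells reached 42.1 ± 0.0698, 66.7 ± 0.0181, 81 ± 3 and 86.3 ± 0.31. K36M cells were thus ahead by 10.8, 30.1, 41.2 and 37.1 points, and by 29.8 points over the 4 days (exact two-sided permutation test of genotype within day, all relabellings, p = 0.00154, the smallest it can give). K36M MEFs stood at 3.63 ± 0.13 at d0 and 7.36 ± 0.0346 without OKSM, WT MEFs without OKSM at -0.686 ± 0.271, and K36M iPSCs at 95.7 ± 1.92. Among genes that differed in both comparisons, 87.5% of 7898 had moved in K36M in the direction of the WT iPSCs over d2 to d8.

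**Figure D1:**
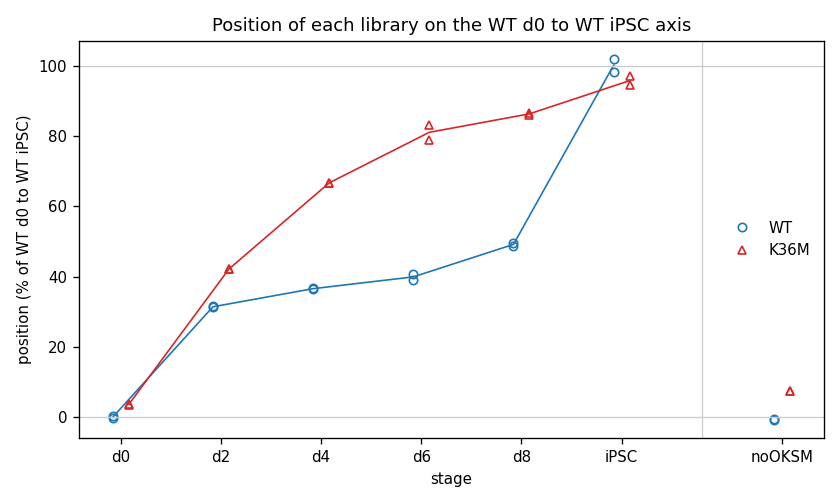
Position of each library on the WT d0 to WT iPSC axis (y axis, percent of the distance) by stage (x axis), with WT libraries as circles and K36M libraries as triangles, and lines through the mean of the 2 libraries of d0 to iPSC. K36M cells lie above WT cells at d2, d4, d6 and d8, for example 66.7 against 36.5 at d4, and the genotypes lie close together at d0 and in iPSCs.

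At d2 epithelial genes were already higher in K36M than in WT. Cdh1 stood at 0.416 ± 0.0112 CPM in WT and 7.94 ± 0.873 CPM in K36M, Esrp1, a splicing regulator of epithelial cells, at 0.337 ± 0.0145 and 9.83 ± 1.32, and Wfdc2, a secreted epithelial protein, at 0.199 ± 0.00802 and 14 ± 2.32 (edgeR adjusted p = 7.28e-10, 2.31e-12 and 3.86e-11). Thbs1, the matrix protein thrombospondin, fell with a log2 fold change of -2.68 ± 0.176 and Cyp1b1, a cytochrome P450, with -2.83 ± 0.136 (edgeR adjusted p = 1.6e-10 and 1.12e-12). Of 25 epithelial genes 19 rose (20 adjusted over the list alone, camera adjusted p = 3.2e-39, adjusted p = 1.29e-06 with an estimated correlation). Of 25 pluripotency genes 12 rose (13 adjusted over the list alone, camera adjusted p = 7.94e-12, adjusted p = 0.0221 with an estimated correlation). Of 11 keratinocyte genes 7 rose (7 adjusted over the list alone, camera adjusted p = 0.00131, adjusted p = 0.0353 with an estimated correlation). Of 20 contractile genes 17 fell (18 adjusted over the list alone, camera adjusted p = 9.22e-20, adjusted p = 0.0112 with an estimated correlation). At d2 trophoblast (6 of 10 rose), skeletal muscle (2 of 8 rose) and primitive endoderm (4 of 9 fell) genes (7, 5 and 4 adjusted over the list alone) passed camera (adjusted p = 0.000775, 0.00982 and 0.0176), but not with an estimated correlation (adjusted p = 0.118, 0.305 and 0.287). Sall4, a pluripotency transcription factor, was 104 times as high (95% counting interval 28.2 to 862) in K36M. Among 24 mesenchymal genes 12 fell and 2 rose (18 adjusted over the list alone, camera adjusted p = 0.000671, adjusted p = 0.477 with an estimated correlation). Among 25 Hox genes 11 fell and 2 rose (15 adjusted over the list alone, camera adjusted p = 0.000206, adjusted p = 0.25 with an estimated correlation). Nanog did not pass the test, at 0.159 ± 0.00641 and 0.255 ± 0.1 CPM (edgeR adjusted p = 0.586). In all 3405 genes differed (1650 higher, 1755 lower), 1432 of them by at least 2-fold (1039 higher, 393 lower). The balance turned with RLE factors, where 53.8% of the genes that differed were higher, against 48.5% in the main fit. Without WT replicate 1 or 2 or K36M replicate 1 or 2 the counts were 2253, 2176, 2097 and 2252. With only the d2 libraries in the fit it was 6818.

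At d4 epithelial and pluripotency genes were both far higher in K36M. Nanog was at 0.26 ± 0.00816 CPM in WT and 54 ± 2.47 CPM in K36M, Cdh1 at 21.6 ± 2.35 and 685 ± 18.5, and Epcam at 8.43 ± 0.306 and 349 ± 9.57 (edgeR adjusted p = 1.31e-18, 5.74e-16 and 2.13e-19). Krt17, a keratin of stratified epithelia, had 0 counts in WT and was at least 210-fold higher in K36M, and the mesoderm regulator T was at least 121-fold higher. Il1rn fell with a log2 fold change of -7.03 ± 0.207, Prelp with -6.15 ± 0.18, and Prrx1 from 379 ± 16.3 to 46.2 ± 0.175 CPM (edgeR adjusted p = 1.9e-17, 1.9e-17 and 8.79e-14). Among 25 epithelial genes 24 rose (24 adjusted over the list alone, camera adjusted p = 3.83e-66, adjusted p = 1.2e-06 with an estimated correlation). Among 25 pluripotency genes 22 rose (23 adjusted over the list alone, camera adjusted p = 5.54e-27, adjusted p = 0.00179 with an estimated correlation). Among 24 mesenchymal genes 20 fell and 2 rose (22 adjusted over the list alone, camera adjusted p = 2.81e-10, adjusted p = 0.188 with an estimated correlation). Among 20 contractile genes 16 fell and 1 rose (18 adjusted over the list alone, camera adjusted p = 4.88e-15, adjusted p = 0.0283 with an estimated correlation). Among 25 Hox genes 21 fell (21 adjusted over the list alone, camera adjusted p = 1.06e-08, adjusted p = 0.0561 with an estimated correlation). Of 20 cell division genes all rose (20 adjusted over the list alone, camera adjusted p = 1.67e-09, adjusted p = 0.0434 with an estimated correlation). Of 19 senescence and p53 target genes 11 fell and 1 rose (13 adjusted over the list alone, camera adjusted p = 0.000181, adjusted p = 0.0486 with an estimated correlation). Markers of other cell types rose as well. Of 11 keratinocyte genes 9 rose and 1 fell (10 adjusted over the list alone, camera adjusted p = 1.77e-09, adjusted p = 0.00128 with an estimated correlation). Of 10 trophoblast genes 8 rose (8 adjusted over the list alone, camera adjusted p = 1.96e-06, adjusted p = 0.0445 with an estimated correlation). At d4 DNA methylation (5 of 7 rose, 1 fell) and endothelial (6 of 10 rose, 1 fell) genes (7 and 7 adjusted over the list alone) passed camera (adjusted p = 0.000846 and 0.0192), but not with an estimated correlation (adjusted p = 0.215 and 0.215). Dnmt3b rose with a log2 fold change of 4.93 ± 0.141. The 8961 genes that differed split into 4589 higher and 4372 lower, 4125 of them by at least 2-fold.

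**Figure D2:**
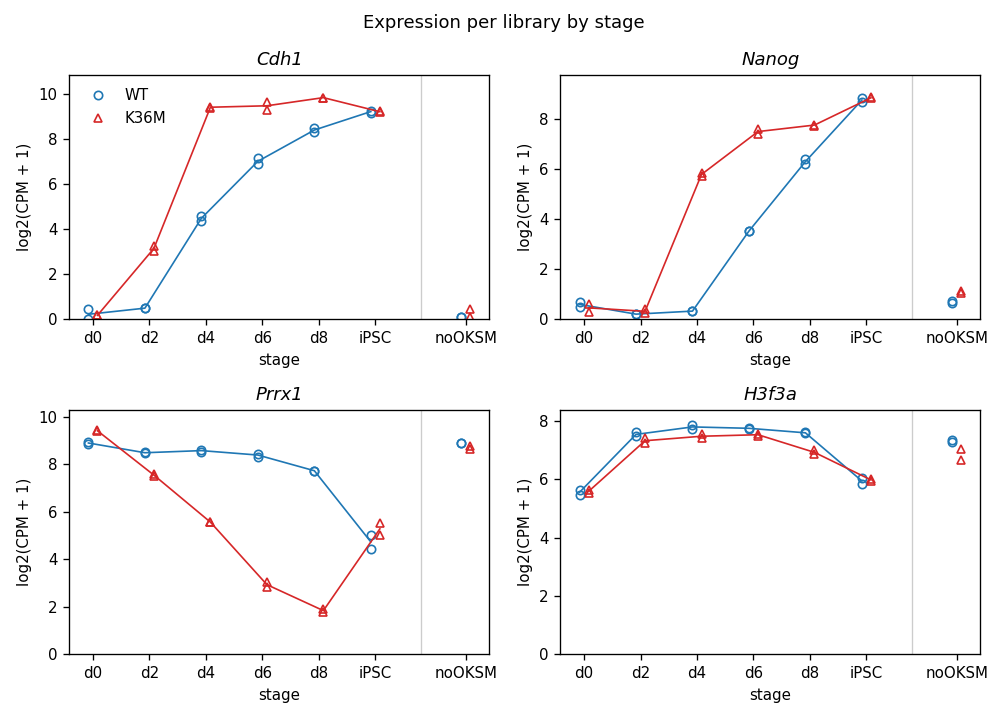
Expression of Cdh1, Nanog, Prrx1 and H3f3a (y axis, log2 of CPM + 1) by stage (x axis), with WT libraries as circles, K36M libraries as triangles and a line through the mean of each pair of libraries from d0 to iPSC. At d4 Nanog stands at 0.26 CPM in WT and 54 CPM in K36M, and Prrx1 at 379 and 46.2 CPM.

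At d6 Nanog was at 10.5 ± 0.144 CPM in WT and 179 ± 17.3 CPM in K36M, and Dppa4, an early embryonic nuclear protein, was 857 times as high (95% counting interval 237 to 7080) in K36M. Twist1 had a log2 fold change of -4.14 ± 0.165, Snai2, another repressor of epithelial genes, -5.14 ± 0.399, and Foxd1, a forkhead factor of stromal cells, -7.93 ± 0.304 (edgeR adjusted p = 1.39e-15, 1.11e-10 and 7.54e-16). Of 25 epithelial genes all rose (25 adjusted over the list alone, camera adjusted p = 2.43e-34, adjusted p = 6.69e-07 with an estimated correlation). Of 25 pluripotency genes all rose (25 adjusted over the list alone, camera adjusted p = 2.85e-20, adjusted p = 0.00428 with an estimated correlation). Of 20 cell division genes all rose (20 adjusted over the list alone, camera adjusted p = 5.4e-10, adjusted p = 0.0343 with an estimated correlation). Of 25 Hox genes all fell (25 adjusted over the list alone, camera adjusted p = 1.66e-10, adjusted p = 0.0434 with an estimated correlation). Of 24 mesenchymal genes 21 fell and 2 rose (23 adjusted over the list alone, camera adjusted p = 3.62e-16, adjusted p = 0.0933 with an estimated correlation). Among 19 senescence and p53 target genes 17 fell and 1 rose (18 adjusted over the list alone, camera adjusted p = 8.94e-05, adjusted p = 0.0454 with an estimated correlation). Among 11 keratinocyte genes 9 rose and 1 fell (10 adjusted over the list alone, camera adjusted p = 3.02e-06, adjusted p = 0.00428 with an estimated correlation). At d6 contractile (17 of 20 fell, 2 rose) and trophoblast (8 of 10 rose, 1 fell) genes (19 and 9 adjusted over the list alone) passed camera (adjusted p = 2.12e-09 and 0.000239), but not with an estimated correlation (adjusted p = 0.0742 and 0.0989). In the same way developmental regulator (17 of 27 fell, 7 rose), skeletal muscle (7 of 8 rose) and endothelial (5 of 10 rose, 3 fell) genes (25, 7 and 8 adjusted over the list alone) passed camera (adjusted p = 0.028, 0.0214 and 0.0498), but not with an estimated correlation (adjusted p = 0.267, 0.38 and 0.312). The last 3 lists were lost in camera with single libraries left out: developmental regulators without K36M d6 replicate 1 or 2 (adjusted p = 0.0833 or 0.397), skeletal muscle without WT d6 replicate 2, K36M d6 replicate 1 or K36M noOKSM replicate 1 or 2 (0.0743, 0.0517, 0.0506 or 0.0511). Endothelial genes were lost without WT d0 replicate 1 or 2, WT d6 replicate 1 or 2, K36M d6 replicate 1 or K36M noOKSM replicate 2 (0.051, 0.0516, 0.0736, 0.0551, 0.0582 or 0.05). Among 16 glycolysis genes 13 rose and 1 fell (14 adjusted over the list alone, camera adjusted p = 0.000346, adjusted p = 0.43 with an estimated correlation), led by Slc16a3 with 4.98 ± 0.195 and the glucose transporter gene Slc2a1 with 2.46 ± 0.105. In all 12013 genes differed (6313 higher, 5700 lower, 6522 by at least 2-fold), or 7731 with only the d6 libraries in the fit. A correction for transcript length and GC content kept 83.7% of them in the same direction and turned the direction of 361. K36M d6 replicate 1 differed from replicate 2 more than any other pair of replicates, with an SD of the log2 difference of 0.653 against 0.331 to 0.419 in the other groups. The difference followed GC content (Spearman rho 0.691 across genes, which are not independent). In WT d0, WT d4 and K36M noOKSM differences between replicates followed transcript length (rho -0.706, -0.714 and 0.67), but GC content little (rho 0.064, 0.05 and 0.099). Among 16 germline genes 12 rose (12 adjusted over the list alone, camera adjusted p = 0.0219, adjusted p = 0.477 with an estimated correlation), and without K36M d6 replicate 1 the list went to camera adjusted p = 0.123.

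At d8 WT cells had gained Nanog (77.5 ± 6.44 CPM) and Cdh1 (339 ± 26.3 CPM), and K36M cells stood at 214 ± 4.68 and 921 ± 4.15 CPM. Zfp42 stood at 1.56 ± 0.267 CPM in WT and 49.2 ± 2.55 CPM in K36M, and Dazl had a log2 fold change of 6.22 ± 0.387 (edgeR adjusted p = 6.63e-12 and 3.71e-12). Col1a1, the main fibroblast collagen, was at 591 ± 48.6 CPM in WT and 35.8 ± 4.92 CPM in K36M, Thy1, a fibroblast surface protein, at 126 ± 17.5 and 11.9 ± 0.347, and Prrx1 at 211 ± 0.91 and 2.58 ± 0.222 (edgeR adjusted p = 2.58e-12, 3.22e-14 and 2.43e-17). Among 24 mesenchymal genes 21 fell (21 adjusted over the list alone, camera adjusted p = 1.35e-21, adjusted p = 0.0434 with an estimated correlation). Among 25 Hox genes all fell (25 adjusted over the list alone, camera adjusted p = 5.72e-17, adjusted p = 0.0112 with an estimated correlation). Among 19 senescence and p53 target genes 16 fell (17 adjusted over the list alone, camera adjusted p = 2.19e-07, adjusted p = 0.0112 with an estimated correlation). Of 25 epithelial genes 22 rose and 1 fell (23 adjusted over the list alone, camera adjusted p = 2.87e-12, adjusted p = 0.000716 with an estimated correlation). Of 25 pluripotency genes 24 rose (24 adjusted over the list alone, camera adjusted p = 1.17e-13, adjusted p = 0.0112 with an estimated correlation). Of 16 germline genes 15 rose (15 adjusted over the list alone, camera adjusted p = 6.14e-08, adjusted p = 0.0989 with an estimated correlation). Of 19 interferon response genes 14 rose and 1 fell (15 adjusted over the list alone, camera adjusted p = 0.0132, adjusted p = 0.477 with an estimated correlation). At d8 trophoblast (8 of 10 rose, 1 fell), skeletal muscle (7 of 8 rose) and contractile (17 of 20 fell, 2 rose) genes (9, 7 and 20 adjusted over the list alone) passed camera (adjusted p = 0.000837, 0.00937 and 2.01e-09), but not with an estimated correlation (adjusted p = 0.114, 0.305 and 0.0807). In the same way cell division (19 of 20 rose) and glycolysis (11 of 16 rose) genes (19 and 11 adjusted over the list alone) passed camera (adjusted p = 1.83e-06 and 0.0017), but not with an estimated correlation (adjusted p = 0.0946 and 0.477). Likewise developmental regulator (15 of 27 fell, 10 rose) and DNA methylation (5 of 7 rose, 1 fell) genes (25 and 6 adjusted over the list alone) passed camera (adjusted p = 0.0363 and 0.0401), but not with an estimated correlation (adjusted p = 0.255 and 0.441). DNA methylation genes were lost in camera without WT d8 replicate 1 (adjusted p = 0.0911). Developmental regulators were lost without WT d4 replicate 1, K36M d6 replicate 1 or 2, or K36M d8 replicate 1 or 2 (0.0801, 0.161, 0.162, 0.0581 or 0.0715). In all 10261 genes differed (5346 higher, 4915 lower, 5145 by at least 2-fold).

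K36M and WT fibroblasts already differed at d0. Tnn, the matrix protein tenascin N, stood at 1.6 ± 0.02 CPM in WT and 36.7 ± 0.261 CPM in K36M (edgeR adjusted p = 3.32e-12). Krt8, a keratin of simple epithelia, stood at 0.83 ± 0.414 and 10.8 ± 0.0771 CPM, and Lgr5, a Wnt co-receptor of stem cells, at 4.44 ± 0.655 and 53.2 ± 0.302 (edgeR adjusted p = 2.85e-12 and 9.77e-12). Rspo3, a Wnt agonist, fell with a log2 fold change of -3.22 ± 0.288, and Lyz2, the lysozyme of macrophages, from 26.2 ± 3.04 to 4.76 ± 0.409 CPM (edgeR adjusted p = 4.23e-08 and 8.18e-08). Of 13 macrophage genes 8 fell (10 adjusted over the list alone, camera adjusted p = 2.48e-09, adjusted p = 0.000519 with an estimated correlation), and these moved together with the following groups. Of 24 mesenchymal genes 10 rose (13 adjusted over the list alone, camera adjusted p = 3.55e-06, adjusted p = 0.322 with an estimated correlation). Of 20 contractile genes 12 fell and 2 rose (16 adjusted over the list alone, camera adjusted p = 0.000162, adjusted p = 0.271 with an estimated correlation). Of 8 cartilage and bone genes 5 rose (5 adjusted over the list alone, camera adjusted p = 0.000536, adjusted p = 0.0888 with an estimated correlation). Of 7 DNA methylation enzymes 4 rose (4 adjusted over the list alone, camera adjusted p = 0.00157, adjusted p = 0.255 with an estimated correlation). Of 20 cell division genes 7 rose (9 adjusted over the list alone, camera adjusted p = 0.00179, adjusted p = 0.287 with an estimated correlation). Of 19 senescence and p53 target genes 7 fell and 1 rose (10 adjusted over the list alone, camera adjusted p = 0.013, adjusted p = 0.194 with an estimated correlation). In all 2694 genes differed (1287 higher, 1407 lower, 831 by at least 2-fold). Without WT replicate 1 the count was 1200, and without K36M replicate 1 or 2 it was 1295 or 1467.

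MEFs without OKSM showed the K36M difference in the absence of reprogramming. Krt8 stood at 0.487 ± 0.0035 CPM in WT and 93.6 ± 5.7 CPM in K36M, Krt7 at 5.2 ± 0.688 and 139 ± 17.5, and Ifitm1, an interferon-induced membrane protein, at 0.307 ± 0.137 and 18.7 ± 0.182 (edgeR adjusted p = 2.87e-19, 1.71e-15 and 5.64e-11). Qprt, an enzyme of NAD synthesis, was 635 times as high (95% counting interval 114 to 25100) in K36M. Edn1, the vasoconstrictor endothelin, fell with a log2 fold change of -3.58 ± 0.147 (edgeR adjusted p = 3.21e-14). Among 25 epithelial genes 11 rose and 1 fell (13 adjusted over the list alone, camera adjusted p = 1.43e-06, adjusted p = 0.011 with an estimated correlation). Among 19 interferon response genes 10 rose and 1 fell (13 adjusted over the list alone, camera adjusted p = 0.00137, adjusted p = 0.347 with an estimated correlation). Among 8 cartilage and bone genes 5 rose and 1 fell (6 adjusted over the list alone, camera adjusted p = 0.00107, adjusted p = 0.0946 with an estimated correlation). Among 10 endothelial genes 6 rose and 1 fell (7 adjusted over the list alone, camera adjusted p = 0.0109, adjusted p = 0.198 with an estimated correlation). Without OKSM trophoblast (2 of 10 rose, 1 fell) genes (3 adjusted over the list alone) passed camera (adjusted p = 0.0274), but not with an estimated correlation (adjusted p = 0.312). Among 20 contractile genes 10 fell and 3 rose (14 adjusted over the list alone, camera adjusted p = 0.00472, adjusted p = 0.413 with an estimated correlation). Twist1 and Col1a1 had log2 fold changes of 0.04 ± 0.124 and 0.22 ± 0.202, and neither passed the edgeR test (adjusted p = 0.856 and 0.423). In all 5920 genes differed (3084 higher, 2836 lower), 2139 of them by at least 2-fold (1558 higher, 581 lower).

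The K36M difference in MEFs without OKSM and that at d0 overlapped in part. Of 1424 genes that differed in both, 602 were higher in both (234 expected from independent lists), 499 were lower in both (236 expected) and 323 went opposite ways. The size of the K36M difference itself differed between these cells for 4246 genes in the edgeR test of the difference of differences (2173 more positive without OKSM, 2073 more negative, 1661 by at least 2-fold). Without WT d0 replicate 1, K36M d0 replicate 1, WT noOKSM replicate 1 or K36M noOKSM replicate 2 the count was 2301, 2770, 2699 or 2416. After the correction for transcript length and GC content, 73.2% of the 4246 genes kept their call and direction. The K36M difference of Klf4 differed between these cells, with log2 fold changes of 0.46 ± 0.134 at d0 and -1.32 ± 0.137 without OKSM (edgeR adjusted p = 7.83e-07 for the difference). The d0 value of Klf4 alone did not pass the test once any 1 of the 4 d0 libraries was left out (0.43 to 0.49). Library names of the cells without OKSM carry another prefix than all others, in both genotypes. If the prefix marks a preparation series, the series and the cells cannot be told apart, although each K36M to WT difference lies within 1 prefix.

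As passaged iPSCs the genotypes were close. Nanog stood at 429 ± 31.1 CPM in WT and 456 ± 7.92 CPM in K36M and Cdh1 at 599 ± 26.7 and 596 ± 9.33, and neither difference passed the edgeR test (adjusted p = 0.838 and 1). Zfp42 was higher in K36M, at 248 ± 16.2 against 82.2 ± 0.681 CPM, and Calml4, a calmodulin-like protein, had a log2 fold change of 2.14 ± 0.195 (edgeR adjusted p = 0.000108 and 1.13e-06). Kbtbd11, a BTB-kelch protein, fell with a log2 fold change of -3.66 ± 0.321 (edgeR adjusted p = 4.09e-07). Among 19 interferon response genes 4 rose (11 adjusted over the list alone, camera adjusted p = 2.41e-12, adjusted p = 0.0434 with an estimated correlation). Gbp3, a guanylate-binding protein, was among them, with a log2 fold change of 1.26 ± 0.198, which was 1.10 and no longer past the test without WT replicate 1. Among 25 epithelial genes 2 rose (4 adjusted over the list alone, camera adjusted p = 0.000131, adjusted p = 0.0311 with an estimated correlation). Other lists shifted in the camera test with few members past the test of single genes, and did not pass with an estimated correlation. Among 24 mesenchymal genes 1 rose (3 adjusted over the list alone, camera adjusted p = 2.36e-06, adjusted p = 0.312 with an estimated correlation). Among 20 contractile genes 1 rose (4 adjusted over the list alone, camera adjusted p = 0.000108, adjusted p = 0.267 with an estimated correlation). Among 16 glycolysis genes none passed the test (3 adjusted over the list alone, camera adjusted p = 6.91e-07, adjusted p = 0.269 with an estimated correlation), with the list lower in K36M as a whole. Among 19 senescence and p53 target genes 1 rose (2 adjusted over the list alone, camera adjusted p = 0.00472, adjusted p = 0.127 with an estimated correlation). Among 12 neuronal genes 1 rose (3 adjusted over the list alone, camera adjusted p = 0.0233, adjusted p = 0.267 with an estimated correlation). Without WT replicate 1 the mesenchymal, senescence and neuronal lists went to camera adjusted p = 0.615, 0.0785 and 0.101. In all 211 genes differed (128 higher, 83 lower, 74 by at least 2-fold), 60.7% of them higher in K36M, against 1397 genes and 47.2% with only the iPSC libraries in the fit. Without WT replicate 1 or 2 or K36M replicate 1 or 2 the share was 53.6%, 78.5%, 74.8% and 61.8%. The count was 56 without WT replicate 1, 131 without K36M replicate 1 and 55 without K36M replicate 2, and it was 447 without a filter, 318 with DESeq2 and 630 after a correction for transcript length and GC content.

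The genotype difference changed with stage for most genes. In a joint edgeR test of d2, d4, d6, d8 and iPSCs against d0, it differed for 12833 of 16932 genes, 7934 of them by at least 2-fold at 1 or more stages. Thy1, for example, was higher in K36M at d0, with a log2 fold change of 0.44 ± 0.138 (edgeR adjusted p = 0.0302), and lower at d8, with -3.41 ± 0.161 (edgeR adjusted p = 1.11e-12 for the change with stage). The d0 value of Thy1 alone did not pass the test once any 1 of the 4 d0 libraries was left out (0.37 to 0.52). Differences at d4 and d6 shared their sign for 93.7% of 7434 genes that differed at both, and those at d6 and d8 for 90.9% of 8246, comparisons that share no library.

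**Figure D3:**
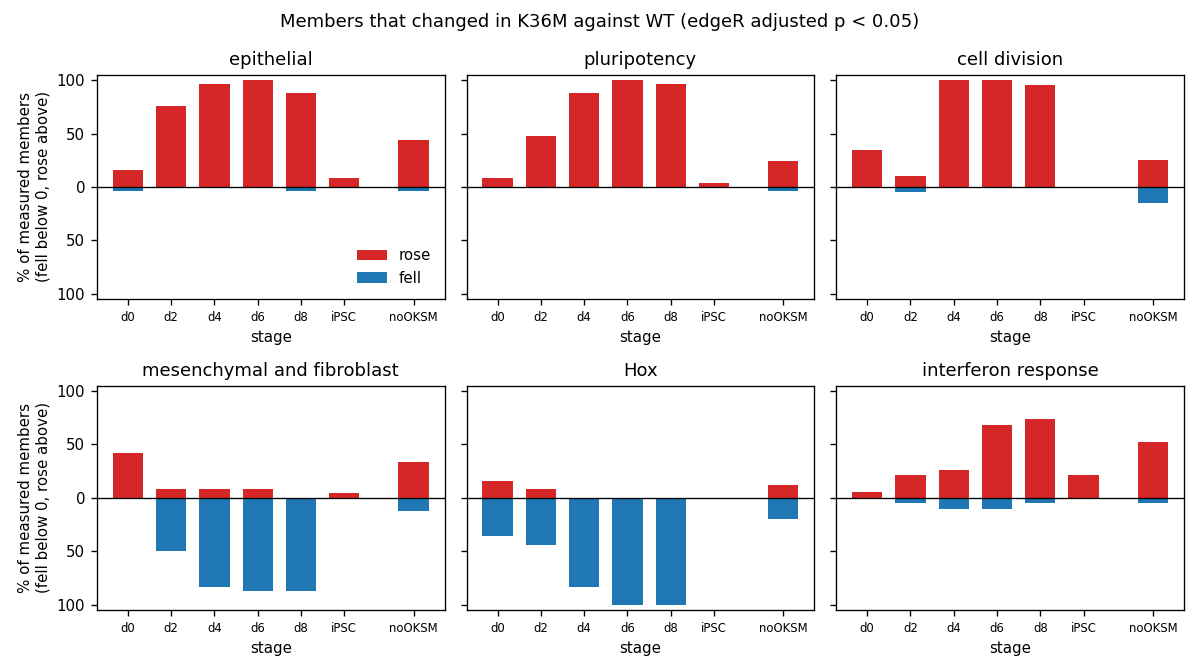
Members that rose (bars above 0) and fell (bars below 0) in K36M against WT at each stage (x axis), as a percentage of the measured members (y axis), in 6 gene lists. At d6 all 25 measured epithelial genes rose and all 25 Hox genes fell, and in iPSCs 2 epithelial genes rose and no Hox gene passed the test.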

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

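The tests of K36M d6 replicate 1, of the Y-linked genes and of macrophages at d0, and the count of genes that went opposite ways at d0 and without OKSM, were chosen only after the results were seen, while the d0 test of length and GC content and the relabelling of genotypes were written down before their results.

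The K36M difference was tested for change between stages and changed for 12833 of 16932 genes (75.8%) over d0 to iPSC. Among them were 69 of the 72 genes whose K36M to WT test result or fold the text gives. The rule for naming genes favours large changes in single contrasts, so their share is not a separate result. The K36M difference also differed between MEFs without OKSM and d0 MEFs for 4246 genes, of which 73.2% kept their call and direction after the length and GC correction. Klf4 was -1.59 (log2, K36M against WT) at d6 and 0.46 at d0 (edgeR adjusted p = 4.08e-08 for the change with stage). Twist2, a mesenchymal transcription factor, was -3.45 at d6 and 0.42 at d0 (edgeR adjusted p = 9.34e-10), and Thy1 was -3.41 at d8 and 0.44 at d0 (edgeR adjusted p = 1.11e-12). The d0 values alone did not pass the test once 1 d0 library was left out, any of the 4 for Klf4 (0.43 to 0.49) and Thy1 (0.37 to 0.52), and WT replicate 2 or K36M replicate 1 or 2 for Twist2 (0.33, 0.48 or 0.37). Chance was tested by relabelling single libraries over d2 to d8. Among 100 of the 648 distinct relabellings of genotype within day, only the real one reached 9328 genes. The highest other reached 8272 with 3 of the 4 days as labelled, and the median of the others was 0. This argues against chance between single libraries. Replicates may share a culture, so chance differences between cultures or MEF isolates cannot be excluded by it.

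K36M d6 replicate 1 stood apart from replicate 2. The difference between them followed GC content across genes (Spearman rho 0.691), so a bias by GC content or transcript length may account for part of it. The trend with GC content was stronger in this pair than in any other group, with WT d6 next (rho 0.471). Trends with transcript length were stronger in WT d0, WT d4 and K36M noOKSM (rho -0.706, -0.714 and 0.67) than in this pair (-0.298). A correction took the SD of the replicate difference, on log2 of CPM + 1, only from 0.467 to 0.384, while the other groups then lay between 0.127 and 0.195, which argues against a smooth trend with length and GC content as the whole difference. Y-linked genes were lower in replicate 1 (median log2 ratio -1.26), and so were their X-linked partners (median log2 ratio -1.32). Among the partners Kdm5c hardly fell (102 CPM in replicate 1, 106 in replicate 2), while its Y-linked counterpart Kdm5d did (19.1 and 40 CPM). The fall of the Y-linked genes thus does not by itself point to loss of the Y chromosome. A bias in this library could lower both groups, so the test cannot exclude such loss from part of its cells. Further progress of this replicate toward iPSCs stays open: at fixed length and GC content the correlation with the WT series was 0.128, between the bounds set for yes and no. No biological explanation beyond these was tested.

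In WT iPSC replicate 1 the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty were lower than in replicate 2, with a median ratio of 0.482 (log2 -1.05). The K36M iPSC pair went the same way to a lesser extent (median ratio 0.772), and Kdm5d was lower in all 4 iPSC libraries (3.36 to 8.28 CPM) than in the others (19.1 to 56.6 CPM). In the WT pair the 4 log2 ratios lay within 0.37 of each other, as one common factor would give, so loss of the Y chromosome from a larger share of those cells may account for it. Female cells stay open: Xist was lower in replicate 1 (log2 -0.46), where more female cells would raise it, but it differed no more than between the K36M iPSC libraries (-0.6). In both WT d0 libraries Xist was at 0 CPM, so female cells were not seen among those MEFs. A length or GC bias is argued against by the X-linked partners, which differed by 0.08 in the median. No other biological explanation was tested.

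K36M and WT MEFs differed in 2694 genes at d0, where H3f3a was at 46.2 and 47.1 CPM (log2 0.03, edgeR adjusted p = 0.93). Of these genes 65.2% had the same sign in MEFs without OKSM (73.2% after the length and GC correction), so K36M made before induction and acting as in those cells stays open for a part of them. Acting so throughout, it would leave few genes going opposite ways, with a bound set at 10%, yet 22.7% of the 1424 genes that differed in both did (17.9% of 2066 after the correction), which argues against it as the whole cause. Fewer macrophages (Lyz2 was at 26.2 CPM in WT and 4.76 in K36M) would raise the genes of the remaining cells by 1 common factor, yet 107 genes at 5 CPM or more in K36M rose at least 2-fold beyond the median of the mesenchymal list (log2 0.37). They would not lower genes of contractile fibroblasts, yet 12 of 20 fell. Both argue against fewer macrophages as the whole cause of the higher and of the lower genes, and a part in the lower genes stays open. A length or GC bias as the whole cause is argued against because 87% of the genes kept their call and direction after the correction. A difference between the MEF isolates or cultures stays open and was not tested.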

How the results depend on the processing

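The correction for length and GC content and the fits without d6 were chosen after the data were seen, the other alternatives before. Of 1902 alternative values for the named gene results, 1868 kept direction and side of the threshold, 20 lost the call, 1 gained it and 13 changed sign. Those 13 were of differences that had not passed the test: Cdh1 in iPSCs (0.00 with only the compared groups, 0.01 after the length and GC correction, 0.04 and 0.01 with 1 library left out), Pou5f1 at d2 (0.00 with RLE factors and with DESeq2, -0.13 to 0.06 with 1 library out, among them 0.03), Twist1 without OKSM (-0.14 after the correction), Klf4 at d2 (-0.16 to 0.02), Col1a1 without OKSM (-0.05 to 0.45) and H3f3a at d0 (-0.06 to 0.12, among them -0.02), the last 3 with 1 library out.

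Counts at a 2-fold threshold were lower by construction: 831 at d0, 1432 at d2, 4125 at d4, 6522 at d6, 5145 at d8, 74 in iPSCs, 2139 without OKSM, 4069 over d2 to d8, 4626, 4742, 5013 and 5723 for WT d2, d4, d6 and d8 against d0, 7934 for the change with stage and 1661 for noOKSM against d0. With only the compared groups in the fit, d2 gave 6818, d6 7731 and iPSC 1397 genes, and the share of higher genes in iPSCs went from 60.7% to 47.2%. The iPSC count was also 447 without a filter, 318 with DESeq2 and 630 after the correction. With an estimated correlation 28 in place of 82 list tests passed. Of the 82 passing list tests, 6 were lost after the length and GC correction, 3 with the replicate block, 3 without a filter and 1 with RLE factors. The causes of these shifts were not tested.

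With 1 library left out, its lone partner is assumed to vary like the other groups. Total counts of genes that differed then ran from 1200 to 2754 at d0, 2097 to 2253 at d2, 55 to 251 in iPSCs and 2301 to 4788 for noOKSM against d0. The totals of all other contrasts stayed within 1.5 times. The number of genes lower in K36M without OKSM moved further than that. Counts at a 2-fold threshold were not refitted in this way. Replicate numbers did not pair the libraries: the correlation of same-numbered deviations between genotypes ran from -0.057 to 0.131 by stage. With the replicate block 9161 genes differed over d2 to d8, and 2714 at d0. With the average of the 4 days in the fit of all groups 11868 genes differed. The score difference of 29.8 ran from 26.0 without d6 (exact permutation, 216 relabellings, p = 0.00926) to 34.5 with medians. Genes that differed over d2 to d8 were kept in the same direction for 97.2% with RLE factors, 97.9% with DESeq2, 94.8% after the correction and 71.5% with the 5 CPM filter, which tests fewer genes. At d6 the correction kept 83.7% of the genes and turned the direction of 361. For noOKSM against d0 it kept 73.2%.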

Other observations

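The correlation with 3' UTR length and the correction for length and GC content below were chosen only after the results were seen, the other tests before. Lum, a collagen-binding proteoglycan of the fibroblast list, went against most of that list in K36M: it was 30.9 times as high (95% counting interval 10.2 to 153) at d2 and 26 times as high (95% counting interval 6.78 to 222) at d4, and without OKSM its log2 fold change was 4.17 ± 0.327 (edgeR adjusted p = 2.4e-07, 1.66e-06 and 1.18e-09). Pdgfra, a receptor of mesenchymal cells, was higher in K36M MEFs, with 1.84 ± 0.181 at d0 and 2.54 ± 0.187 without OKSM (edgeR adjusted p = 1.97e-07 and 4.8e-10). The cardiac regulator Nkx2-5 was 136 times as high (95% counting interval 37.3 to 1130) in K36M MEFs without OKSM, while Tbx20, another heart regulator, and Tbx2 fell there, with -2.89 ± 0.346 and -1.86 ± 0.229 (edgeR adjusted p = 6.84e-07 and 1.01e-06). Acan, which codes for the cartilage proteoglycan aggrecan, rose in the same cells, with 3.22 ± 0.254, and the cartilage collagen gene Col9a1 was 183 times as high (95% counting interval 50.3 to 1520), whereas Sox9, a regulator of cartilage, fell with -1.43 ± 0.172 (edgeR adjusted p = 1.22e-09 and 5.07e-10 for the risen, 7.23e-07 for the fallen).

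The imprinted list did not pass the test over d2 to d8 or without OKSM, where 8 of 20 genes rose and 4 fell (12 adjusted over the list alone, camera adjusted p = 0.349), but single members changed. H19, an imprinted noncoding RNA, was higher in K36M MEFs without OKSM, with 2.93 ± 0.318, and Snrpn rose at d4 and d6, with 1.79 ± 0.0891 and 2.25 ± 0.0902 (edgeR adjusted p = 7.49e-07, 1.19e-13 and 1.51e-15). Of 18 H3K36 and PRC2 enzymes 6 fell without OKSM (6 adjusted over the list alone, camera adjusted p = 0.0498, adjusted p = 0.529 with an estimated correlation). The camera value was 0.0549 without WT noOKSM replicate 1, 0.172 without K36M noOKSM replicate 2, and 0.057 or 0.0531 without K36M d6 replicate 1 or 2. Among them Ezh2, which methylates H3K27, was at -0.52 ± 0.0814 without OKSM, and its cofactor Jarid2 at -0.66 ± 0.102 there and 1.66 ± 0.0953 at d4 (edgeR adjusted p = 2.71e-05, 2.19e-05 and 1.16e-12). At d6 8 of the 18 fell and 5 rose (13 adjusted over the list alone, camera adjusted p = 0.697). Among those that fell, Ash1l, a methyltransferase, was at -2.48 ± 0.243 and Kdm4a, a demethylase, at -1.44 ± 0.0868 (edgeR adjusted p = 1.6e-08 and 1.56e-12). K36M d6 replicate 1 stood apart from replicate 2, and after the correction for length and GC content Ash1l was at -1.29 and Kdm4a at -1.04, both still past the test. Across genes, which are not independent, the K36M log2 fold change correlated with 3' UTR length with a Spearman rho of 0.232 at d0, -0.125 at d2, -0.103 at d4, -0.35 at d6, -0.044 at d8, -0.057 in iPSCs and -0.274 without OKSM. Differences between replicates of the same group gave rho from -0.417 (WT d0) to 0.377 (K36M noOKSM). The K36M values lie within that range, so they cannot be told apart from trends between libraries. Xist, the RNA that silences an X chromosome, was read in each library as a check and lay between 25.9 and 42.8 CPM in the 4 iPSC libraries, which also held Y-linked RNA.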
